A study of Mus musculus with 40 samples.

How the data were processed

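Single-cell RNA sequencing of mouse testis was analysed, with 20 libraries named Pachytene and 20 named Metaphase I, each made from 1 cell of C57BL/6J mice aged 6 to 8 weeks. Per the labels' protocols, spermatocytes were fractionated by centrifugal elutriation, which sorts cells by size and sedimentation, and progression to metaphase I was induced in culture with 4 µM okadaic acid for 5 h. Okadaic acid inhibits the protein phosphatases PP1 and PP2A. The same protocol text stands on all 40 libraries, and the Metaphase I libraries were taken as the treated ones from their names. Stage, drug and the added time in culture are therefore 1 contrast. Whether the Pachytene cells were cultured without the drug is not given in the sources used here.

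Per the labels' protocols, libraries followed a modified STRT-seq method, in which oligo(dT) primers with a barcode for each cell start the cDNA. The cDNA was amplified for 20 PCR cycles, pooled over cells, amplified for 4 more cycles, and its 3' ends were kept and sequenced with 150 bp paired reads. UMI-tools, STAR and featureCounts were used with the GRCm38 build, per the submitters' processing notes, without versions. The deposited table holds whole-number counts per gene for 55492 genes, per the file headers with exon coordinates as featureCounts writes them. Whether a count is a read or a molecule after removal of PCR copies, the strand setting and the annotation release are not given in the sources used here. Without a stated strand setting, a gene and a partner on the opposite strand cannot be told apart, and counts of near-identical genes are uncertain. Of the symbols, 53292 (96.0%) are also in GENCODE M21, which is on GRCm38, and 98.2% of these have the same chromosome, start and end there. Coordinates are those of the deposited table, 1-based, from the first exon start to the last exon end. All 40 value columns matched a library by name.

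The labels name no animal, donor or culture, so the 20 cells of a group were taken as 1 sample and no test between the groups was made. No p-value is given. Counts were summed over the cells of a group and divided by the summed total, giving CPM, the counts per 1000000. The log2 ratio is Metaphase I over Pachytene, with a pseudocount of 1 CPM on each group. A summed count has an exact Poisson interval, a fold has an exact conditional binomial interval, and a share has an exact (Clopper-Pearson) binomial interval, all at 95%. These cover counting error only and not the spread between cells or animals, and they are too narrow if counts are reads and not molecules. A fold against a group with 0 counts was computed against a floor of 3 counts over the group. Medians, quartiles and ranges over cells are given as description.

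Before the data were examined, 27 gene lists with 568 entries were written, of which 566 matched a symbol in the table. A member was measured when its summed count over both groups reached 20. Each list's median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 20 bins. Such a percentile describes these cells and is no test. Named genes followed a rule of size. Among genes with a summed count of 100 or more and a count in at least 50% of the cells of the higher group, it took the 12 highest and the 12 lowest log2 ratios whose ratio of mean CPM per cell was also over 2-fold the same way. Mitochondrial genes, ribosomal protein genes and unnamed gene models were left out. It added up to 3 measured members of each list with the largest ratio and the 5 most abundant genes of each group. Genes outside this rule are said to have been chosen after their values were seen. Of the genes the rule took when repeated without some libraries, only examples are named, and 1 is not reported here.

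Detected genes were also counted after each cell was thinned to 340000 counts, the 10th percentile of the totals rounded down, which left out 1 Pachytene and 3 Metaphase I cells. Principal components used log2(CPM + 1) of the 11047 genes with a summed count of 100 or more. The libraries of a group were compared in pairs by a chi-square statistic per degree of freedom over these genes. It was 2.69 or more in every pair, where sampling noise alone gives about 1, so no library was counted as a copy of another of its group. Pairs across the groups were not compared in this way. No doublet caller was run on 40 cells.

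Alternatives planned before the data were examined were equal weight per cell, TMM and median-of-ratios scaling, totals without mitochondrial and ribosomal protein genes, a pseudocount of 10 CPM, other count minimums, thinning, omission of the deepest cell of each group and of each cell in turn. Chosen after seeing the data were the ratio of medians over cells, Metaphase I replicate 13 as an omission to report by itself, omission of Metaphase I replicate 19, and omission of the 8 libraries in which X-linked genes held over 0.3% of counts. The code was tested on simulated Poisson counts with 200 altered genes, 50 per fold size, in the comparison of the 2 groups, with 16181 genes in the list step. The conditional interval covered the true fold for 100% of genes raised 2-fold, 98% of those raised 4-fold, 92% at 0.5-fold and 94% at 0.25-fold. In the list step, 15 genes raised 2-fold ranked at the 100th percentile of random lists. A list of 15 unchanged genes ranked at the 95.0th, so a high percentile can also arise without a true difference. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, with edgeR 4.0.16 in R 4.3.3 for the TMM factors and matplotlib 3.10.9 for plots.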

Results

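Transcript counts were measured in 40 single cells from mouse testis, 20 named Pachytene and 20 named Metaphase I. In pachytene of the first meiotic prophase, homologous chromosomes are fully paired and the X and Y are silenced. At metaphase I the pairs are aligned on the spindle. The comparison asks which transcripts differed between spermatocytes at pachytene and those driven to metaphase I with okadaic acid. The total per cell ran from 165048 to 2325564 counts in Pachytene (median 730979, quartiles 564017 and 887429) and from 198117 to 1497037 in Metaphase I (median 540662, quartiles 391169 and 937716). The sums were 17663240 and 13709617 counts. Each group is 1 sample with no replicate animal, so differences are described and not tested, and intervals cover counting error only.

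The transcriptomes of the groups were close to each other. Across 16174 genes with at least 20 summed counts, the median log2 ratio was -0.00, with quartiles of -0.40 and 0.38. Of these genes 8.5% were over 2-fold higher in Metaphase I and 9.8% lower. Without the 8 libraries over 0.3% X-linked counts the shares were 5.7% and 3.7%. Numbers of list members over 2-fold are to be read against these shares. The most abundant transcripts were shared. Ldhc, the testis-specific lactate dehydrogenase subunit (chromosome 7, 46861203 to 46878142), had a median of 17768 CPM per cell in Pachytene and 18410 in Metaphase I. Meig1, needed for later spermatid development, had 5982 and 4879 CPM. Ldhc and Meig1 were among the 5 most abundant genes of each group, as were the mitochondrial rRNA mt-Rnr2 and CT010467.1, a locus on chromosome 17 that GENCODE M21 annotates as rRNA. The ribosome biogenesis factor Lyar, among these 5 in Pachytene, had 5406 and 5156 CPM. The poly(A)-binding protein gene Pabpc1, among these 5 in Metaphase I, had 4605 and 4898.

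Cells did not separate by group. The median Spearman correlation across 11047 genes was 0.78 between 2 Pachytene cells, 0.74 between 2 Metaphase I cells and 0.76 between cells of different groups. The most similar cell was of the same group for 9 of 20 Pachytene and 9 of 20 Metaphase I cells. PC1 held 31.6% of the variance and PC2 11.1%. The genes with the highest loadings on PC1 included the spermatid genes Smcp, Hmgb4, Ropn1, Hils1 and Cylc2, chosen after their loadings were seen. The median number of detected genes was 10868.5 in Pachytene and 10656 in Metaphase I, and after thinning it was 9947 (range 8464 to 10919, 19 cells) and 9886 (range 7902 to 11403, 17 cells).

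**Figure D1:**
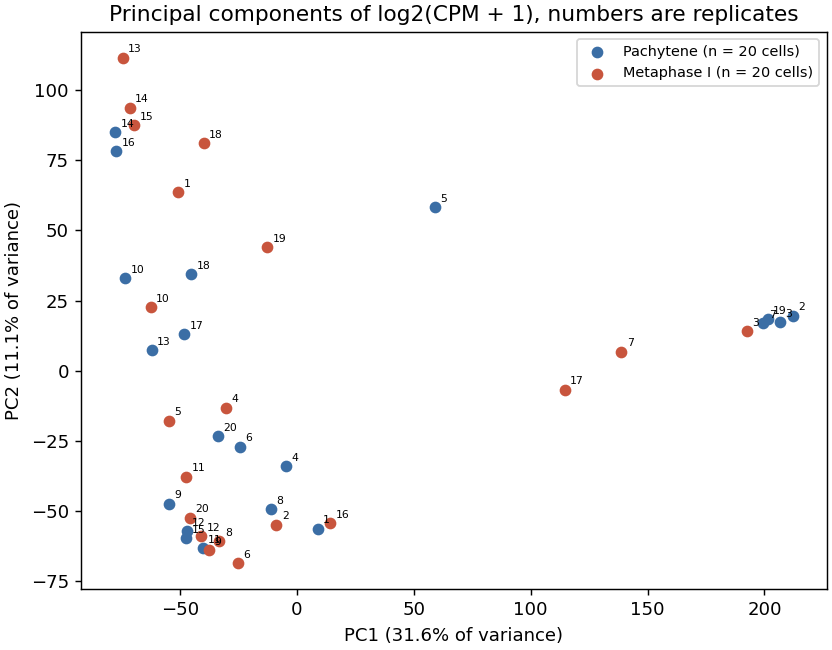
Each point is 1 cell on PC1 (31.6% of variance, x axis) and PC2 (11.1%, y axis) of log2(CPM + 1), blue for Pachytene and red for Metaphase I, with its replicate number. Cells of both groups lie at both ends of each axis.

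X-linked transcripts were rare in most cells of both groups. The median share of counts from X-linked genes was 0.0407% in Pachytene and 0.0512% in Metaphase I. Shares over 0.3% were found in 4 libraries of each group. In Pachytene replicates 2, 3, 7 and 19 the share was 0.741%, 1.19%, 0.948% and 1.08%, and in Metaphase I replicates 3, 7, 17 and 19 it was 0.837%, 0.470%, 0.490% and 1.48%. Y-linked shares had medians of 0.000960% and 0.000685%. Because of these libraries the share of summed counts was far above the median, at 0.25% X-linked in Pachytene (exact binomial interval 0.248% to 0.252%) and 0.198% in Metaphase I (0.196% to 0.200%). Without them it was 0.0411% (0.0400% to 0.0422%) and 0.0476% (0.0463% to 0.0488%). The summed Y-linked shares were 0.0215% (0.0208% to 0.0222%) and 0.0120% (0.0114% to 0.0125%), and without the 8 libraries 0.000848% (0.000701% to 0.00102%) and 0.000785% (0.000631% to 0.000966%).

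**Figure D2:**
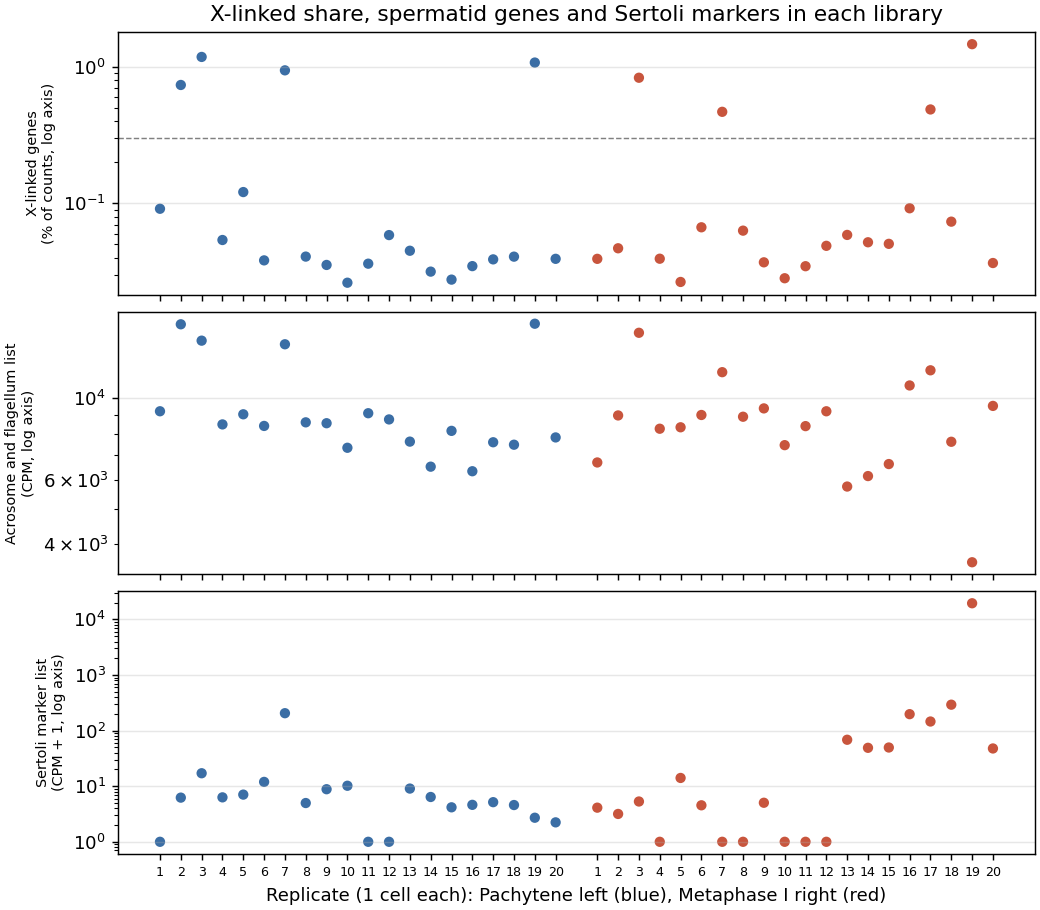
Each point is 1 library (x axis, replicate number, Pachytene left and Metaphase I right), with the X-linked percent of counts (top, dashed line at 0.3%), summed CPM of the acrosome and flagellum list (middle) and of the Sertoli markers (bottom, CPM + 1), all on log axes. Metaphase I replicate 19 reached 19524 CPM of Sertoli markers.

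Metaphase entry genes differed little between the groups. Of 20 measured metaphase entry kinases and cyclins, 0 were over 2-fold higher or lower on the ratio with its pseudocount of 1 CPM, and their median log2 ratio was 0.19 (97.1st percentile of matched random lists). Pkmyt1, an inhibitory kinase of Cdk1, was 1.57-fold higher in the sum (1.31 to 1.87). Ccna2 had 25 counts in Pachytene and 3 in Metaphase I, a log2 ratio of -0.99 with the pseudocount and 6.47-fold lower without it (1.97 to 33.5). Pachytene replicate 7 held 76% of the 25, and without that library Ccna2 was 1.79-fold lower. Over the 40 omissions of a single cell, Ccna2 was over 2-fold lower on the ratio with the pseudocount in 17. The M-phase genes Ccnb1 and Plk1, chosen after their values were seen, varied more within than between groups. Ccnb1 ran from 4.59 to 404 CPM over Pachytene cells (median 170) and from 3.92 to 505 CPM over Metaphase I cells (median 245), and its summed ratio was 1.20-fold (1.13 to 1.26). Plk1 had medians of 104 and 168 CPM.

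Spindle checkpoint genes were over 2-fold higher in the Metaphase I sum about as often as genes at large. Of 26 measured members of the checkpoint and anaphase promoting complex list, 3 were over 2-fold higher in Metaphase I and 0 lower, with a median log2 ratio of 0.19. Over all 16174 genes 8.5% were over 2-fold higher and 9.8% lower. Bub1b, the checkpoint kinase-related protein BubR1 (chromosome 2, 118598211 to 118641591), had 629 counts in Pachytene and 1052 in Metaphase I, 2.15-fold higher (1.95 to 2.38). It was detected in all 20 cells of each group, with a median of 31.2 CPM (quartiles 24.1 and 53.9) in Pachytene and 75.5 (quartiles 54.6 and 85.0) in Metaphase I. Mad2l1 was 2.14-fold higher (1.84 to 2.5) and Anapc4 2.44-fold higher (2.00 to 2.99), with medians of 9.56 and 18.8 CPM for Mad2l1 and 3.70 and 4.02 CPM for Anapc4. Metaphase I replicate 13 held 24.1% of the Bub1b counts of its group, 27.0% for Mad2l1 and 34.5% for Anapc4. Without this cell they were 1.83-fold, 1.76-fold and 1.80-fold higher, and 0 of the 26 were over 2-fold higher. The number was 1 without Pachytene replicate 7 and 5 without Pachytene replicate 16. Without the 8 libraries 1 of the 26 was, and Bub1b had a log2 ratio of 0.97. Among 21 measured centromere and kinetochore genes 1, Cenpt, was over 2-fold higher (2.59-fold, 2.05 to 3.28), and the list median was 0.19. Replicate 13 held 39.9% of its Metaphase I counts, and it was 1.75-fold higher without that cell. Over the single omissions 0 to 2 of the 21 were over 2-fold higher and 0 to 1 lower. Without the 8 libraries 2 were higher, and the list median was 0.12. Of 24 measured cohesin, condensin and shugoshin genes 2 were over 2-fold higher, Smc1a and Top2b, and the median was 0.20. All 84 Metaphase I counts of Smc1a lay in replicate 19, and its log2 ratio without that library was -0.15. Of the 24, 0 were over 2-fold higher without the 8 libraries, with a median of 0.057.

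Recombination genes were higher in the Metaphase I sum. The 23 measured members had a median log2 ratio of 0.49 (100th percentile), with 3 over 2-fold higher and 0 lower, and the same 2 counts were found without the 8 libraries (median 0.50). The median was 0.30 with equal weight per cell, 0.20 with thinned cells and 0.26 for medians over cells. Hfm1, a helicase needed for crossover formation (chromosome 5, 106840192 to 106926321), was 2.62-fold higher (2.32 to 2.97), with medians of 10.9 CPM in Pachytene (quartiles 5.19 and 37.5) and 34.1 in Metaphase I (quartiles 9.29 and 55.4). Msh4, a MutS homolog that acts in crossing over, was 2.83-fold higher (2.27 to 3.54), and Trip13 was 2.46-fold higher (1.85 to 3.29). Metaphase I replicate 13 alone held 37.4% of the summed Hfm1 counts, 44.8% for Msh4 and 40% for Trip13, and without this cell they were 1.84-fold, 1.75-fold and 1.66-fold higher, 0 of the 23 were over 2-fold higher and the list median was 0.24. Without Pachytene replicate 16, 5 were over 2-fold higher. The 10 synaptonemal complex genes had a median of 0.44, with 1 over 2-fold higher, against 0 and a median of 0.06 without replicate 13, and a median of -0.05 when medians over cells were compared. Without the 8 libraries 3 of the 10 were over 2-fold higher (median 0.57, 100th percentile), and without Pachytene replicate 16 there were 2 (median 0.61). Sycp2 was 1.72-fold higher (1.66 to 1.77), but its sum rests in part on single cells. Metaphase I replicate 18 had 5132 CPM and replicate 13 had 1240, against at most 1092 in a Pachytene cell (replicate 14). The 22 piRNA pathway genes had a median of 0.31 with 0 over 2-fold either way, and -0.02 for medians over cells. Of these, 2 were over 2-fold higher without the 8 libraries (median 0.23, 99.9th percentile) and 1 without Pachytene replicate 16.

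Spermatid transcripts were lower in the Metaphase I sum. Of 31 measured acrosome and flagellum genes, 11 were over 2-fold lower and 0 higher (median log2 ratio -0.84, 0th percentile), and of 14 elongating spermatid markers 9 were over 2-fold lower and 0 higher (median -1.40). Akap4, the main fibrous sheath protein of the sperm tail (X, 7067519 to 7078609), was 4.40-fold lower (3.88 to 4.99), and Hmgb4 was 4.39-fold lower (4.03 to 4.78). Odf1, an outer dense fibre gene, was 3.30-fold lower (2.85 to 3.84), but its log2 ratio of medians over cells was 0.31. The transition protein gene Tnp1 was 3.14-fold lower (2.67 to 3.72). Of the 8 libraries over 0.3% X-linked counts, Metaphase I replicate 19 had the lowest acrosome and flagellum level of all 40 libraries, at 3576 CPM, and the other 7 had 11751 CPM or more. Pachytene replicate 7, at 2325564 counts, held 52.7% of the summed Akap4 counts, 61.3% for Hmgb4, 55.9% for Odf1 and 43.8% for Tnp1. Without it they were 2.39-fold, 1.96-fold, 1.67-fold and 2.03-fold lower, and without Metaphase I replicate 3 they were 11.5-fold, 35.6-fold, 8.67-fold and 16.1-fold lower. Over 2-fold lower were 1 acrosome and flagellum gene without Pachytene replicate 7 and 18 without Metaphase I replicate 3, and 3 and 11 elongating spermatid markers. Leaving Pachytene replicate 7 out gave an acrosome and flagellum median of -0.15, and leaving out Metaphase I replicate 3 gave -1.97. For the elongating spermatid markers these were -0.68 and -2.49. Without the 8 libraries, 0 of 31 acrosome and flagellum genes and 4 of 14 elongating spermatid markers were over 2-fold lower, and the medians were -0.17 (1.4th percentile) and -0.60 (0.07th percentile). For medians over cells they were -0.03 and -0.33, with 3 lower and 1 higher of the 31 and 5 lower and 1 higher of the 14. Of 14 spermatid chromatin genes 4 were over 2-fold lower (median -0.32), 1 without Pachytene replicate 7, 6 without Metaphase I replicate 3 (median -0.51) and 2 without the 8 libraries (median -0.085).

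**Figure D3:**
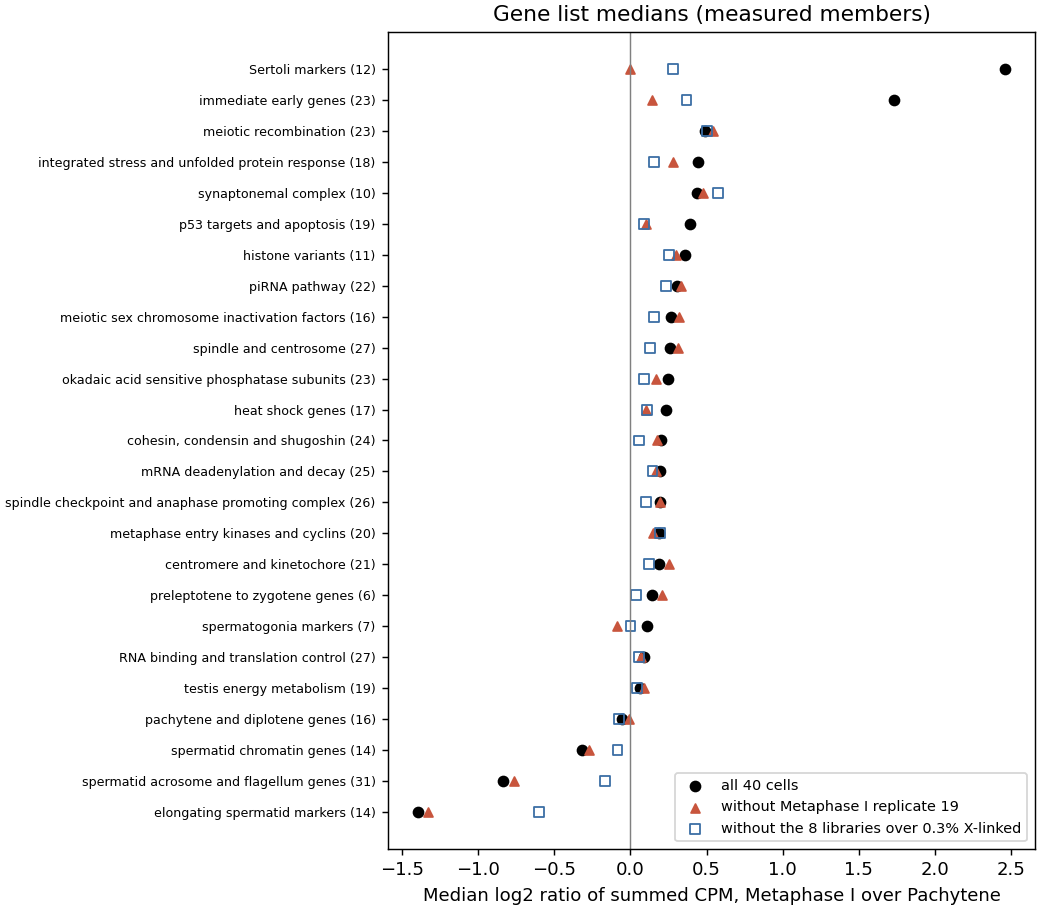
The x axis is the median log2 ratio of summed CPM, Metaphase I over Pachytene, and the y axis is the gene list with its number of measured members, shown for lists of at least 5. Black circles are all cells, triangles leave out Metaphase I replicate 19, and squares leave out the 8 libraries over 0.3% X-linked counts.

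Sertoli markers and immediate early genes were higher in the Metaphase I sum, with most of the counts in 1 library for the genes named here. Of 12 measured Sertoli markers, 10 were over 2-fold higher and 1 lower (median log2 ratio 2.46). Clu, which encodes clusterin (chromosome 14, 65968483 to 65981547), had 19 counts in Pachytene and 7617 in Metaphase I, of which replicate 19 held 96.7%. Vim, the intermediate filament vimentin, had 2 and 1347 counts, with 95.3% in replicate 19. Of 23 measured immediate early genes 14 were over 2-fold higher and 2 lower (median 1.73). The lower ones numbered 4 without Metaphase I replicate 3 and 0 without Pachytene replicate 7. Atf3 had 0 counts in Pachytene and 527 in Metaphase I, 226-fold higher with the floor of 3 counts in place of 0, with 98.9% in replicate 19. Without this library 2 of 12 Sertoli markers were over 2-fold higher and 3 lower, and 2 of 23 immediate early genes were higher and 2 lower, with medians of 0.00 and 0.14 (95.5th percentile for the latter). Leaving out the 8 libraries, replicate 19 among them, gave 3 Sertoli markers higher and 0 lower, with a median of 0.28 (98.8th percentile), and 2 immediate early genes higher and 0 lower, with a median of 0.37 (99.9th percentile). Without Pachytene replicate 7, which held 78.9% of the Clu counts of its group, the Sertoli median was 4.25. Metaphase I replicate 19 also held 76.5% of the Hspd1 counts of its group, 95.0% of those of the small heat shock gene Hspb1 and 95.1% of those of the cell cycle inhibitor Cdkn1a. Over 2-fold higher were 6 of 17 heat shock genes (median 0.24), 8 of 19 p53 and apoptosis genes (0.39) and 4 of 18 integrated stress and unfolded protein response genes (0.45), and without replicate 19 these numbers were 0, 3 and 2. They were 3, 1 and 1 without the 8 libraries, with medians of 0.11, 0.088 and 0.16.

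Of 27 measured spindle and centrosome genes, 5 were over 2-fold higher and 1 lower (median 0.26, 99.8th percentile), and without the 8 libraries 2 were higher and 0 lower (0.13). The higher genes were also 2 without Pachytene replicate 7 alone or Metaphase I replicate 19 alone. Of 23 subunits of okadaic acid sensitive phosphatases 2 were over 2-fold higher and 1 lower (0.25, 98.7th percentile), with a median of 0.089 without the 8 libraries. The higher genes were 1 without Metaphase I replicate 13 or 19 and at most 3 over the single omissions, and the lower ones 0 without Pachytene replicate 6. Of 11 histone variants 2 were higher and 0 lower (0.36, 98.9th percentile), and of 16 sex chromosome inactivation factors 0 were higher and 1 lower (0.27, 98.5th percentile). Over the single omissions 1 to 3 histone variants were higher, and 0 to 2 inactivation factors were lower, 0 without Pachytene replicate 7 and 2 without Metaphase I replicate 19. Without Metaphase I replicate 13 the medians of these lists were 0.066 and 0.063, and without the 8 libraries they were 0.25 and 0.16, with 0 inactivation factors lower. The median was 0.19 for 25 mRNA decay genes, of which 1 was over 2-fold higher (0 without Metaphase I replicate 19) and 0 lower, and 0.09 for 27 RNA binding and translation genes, with 3 higher and 0 lower. It was 0.06 for 19 energy metabolism genes, with 4 higher and 2 lower (1 and 1 without Metaphase I replicate 19, 1 and 0 without the 8 libraries), and -0.06 for 16 pachytene and diplotene genes, with 0 higher and 1 lower. Of 6 preleptotene to zygotene genes 1 was higher and 0 lower (median 0.14, and 0.034 without the 8 libraries). Over the single omissions the higher genes numbered 0 to 2 for mRNA decay, 2 to 4 for RNA binding and translation, 1 to 4 for energy metabolism and 0 to 1 for both prophase lists, and the lower genes 0 to 3 for energy metabolism and 0 to 2 for pachytene and diplotene. The testis histone gene H2bc1 was 5.94-fold higher (4.41 to 8.13). Without the 8 libraries it was 5.50-fold higher (4.08 to 7.53), with 34.6% of its Metaphase I counts in replicate 13. It was 4.15-fold higher when that cell was left out as well. Of markers of other cells, the 7 measured spermatogonia markers had a median of 0.11 (-0.088 without Metaphase I replicate 19), the 3 peritubular, endothelial and blood markers 0.37 (-0.59 without Metaphase I replicate 15), and the 1 measured Leydig marker, Star, 1.94, with 57.3% of its Metaphase I counts in replicate 19.

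The genes at both ends of the fixed rule followed these libraries. All 12 highest genes had over 50% of their Metaphase I counts in replicate 19. They were Clu, Vim, Ctsl, Hspb1, Txn1, Gadd45b, Akap13, Uchl1, Cycs, Eif4ebp1, Gpx1 and Ier3, with log2 ratios from 8.07 to 2.71. All 12 lowest had their highest Pachytene count in replicate 7, the deepest library. They were Tmem132cos, Marchf8, H2bl1, Spaca6, Fam243, BC048562, Mical2, Txndc2, Zfp933, Rbm43, Tppp3 and Tex24, with log2 ratios from -4.00 to -2.11. In CPM, replicate 7 was the highest Pachytene cell for Marchf8 and BC048562. Replicate 19 was above it for H2bl1, Spaca6, Fam243 (284 against 117 CPM), Mical2 and Rbm43. Without the 8 libraries, 8 of the 12 highest and 4 of the 12 lowest were still over 2-fold, and the rule then took 12 and 12 genes of which 0 and 0 were the same. With 16 cells per group, Map3k2, a MAP kinase kinase kinase and 1 of the 12 highest, was 5.38-fold higher (3.75 to 7.91) and was detected in 7 and 15 cells. Metaphase I replicate 13 held 21.2% of its Metaphase I counts. This was the smallest share of a single cell among the 12 highest, and the largest was 68.5%, in Metaphase I replicate 18. The lowest were led by Fev, an ETS transcription factor, with 99 and 9 counts (9.11-fold lower, 4.61 to 20.5). Pachytene replicate 6 held 44.4% of its Pachytene counts and Metaphase I replicate 6 the same share of the 9, and it was 6.08-fold lower without the former and 16.0-fold lower without the latter. Tmed6 was 4.46-fold lower (3.99 to 5.00), but its medians were 21.3 and 14.8 CPM, it was detected in 14 and 15 cells, and Pachytene replicate 8 held 35.6% of the counts of its group. Zfp389 was 3.47-fold lower (2.97 to 4.06), with medians of 63.1 and 14.3 CPM.

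Mitochondrial mRNA was lower in most Metaphase I cells and higher in their sum. The median share of counts was 0.267% in Pachytene (quartiles 0.159% and 0.407%) and 0.123% in Metaphase I (quartiles 0.0912% and 0.224%), while mitochondrial rRNA had medians of 1.84% and 1.55%. The summed mitochondrial mRNA shares were 0.290% and 0.433%, and 0.213% in Metaphase I without replicate 19. Replicates 19 and 18 of Metaphase I had total mitochondrial shares of 17.5% and 11.2%, Pachytene replicate 5 had 7.12% and Pachytene replicate 4 had 0.0643%. Pachytene replicate 5 and Metaphase I replicate 18 also had the highest levels of the rRNA locus CT010467.1, at 65363 and 92132 CPM. Of genes chosen after their values were seen, mt-Co1 had medians of 592 and 222 CPM and mt-Nd1 776 and 262. All mitochondrial genes together held 2.19% of the summed Pachytene counts (2.18% to 2.20%) and 2.97% of those of Metaphase I (2.96% to 2.97%). The Metaphase I share was 2.18% without replicate 19 (2.17% to 2.18%), and the medians over cells were 2.16% and 1.70%. Ribosomal protein genes held 4.45% (4.44% to 4.46%) and 5.00% (4.99% to 5.01%), with medians over cells of 4.25% and 4.08%.

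**Figure D4:**
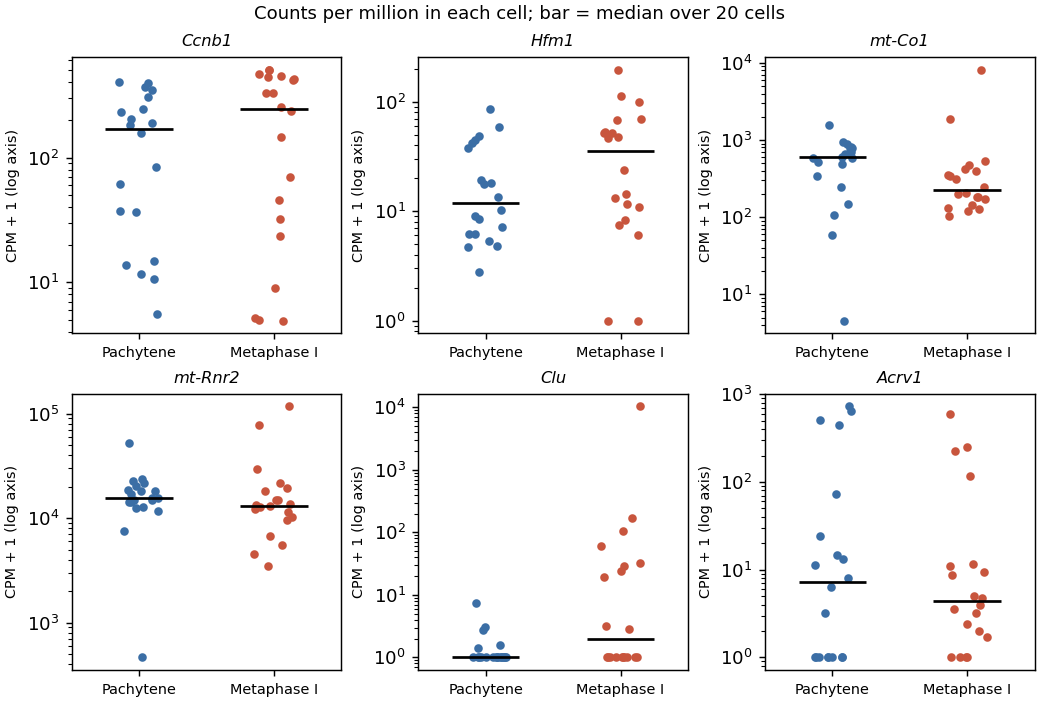
Each point is 1 cell, with the gene's CPM + 1 on a log y axis and the group on the x axis, and the bar is the median over 20 cells. The median of mt-Co1 was 592 CPM in Pachytene and 222 in Metaphase I, and 1 Metaphase I cell stands above the rest for Clu.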

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

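No paired analysis was possible because the results come from no test, and replicate numbers only name cells. The planned fits for summed counts per sample (edgeR with and without the number as a block, DESeq2, other size factors, no filter) were not run, since each library is 1 cell. The omission of Metaphase I replicate 19, the singling out of Metaphase I replicate 13 among the single omissions, the omission of the 8 libraries and the ratio of medians over cells were chosen after the data were seen. Of 27 list medians, 27 kept their sign with TMM, median-of-ratios, totals without mitochondrial and ribosomal protein genes and thinning, 26 with equal weight per cell and without the 8 libraries, 25 without replicate 19, 24 at the lowest of the single omissions and 16 with medians over cells. Of 113 genes taken by the rule or chosen afterwards, 113 kept their sign under these 3 scalings, 101 without replicate 19, 97 without the 8 libraries and 67 with medians over cells. The TMM factors were 0.995 (Pachytene) and 1.005 (Metaphase I), and those of median-of-ratios 0.994 and 1.007. Factors this near 1 could hardly turn a sign, so signs kept under them say little. The cause of the following shifts was not tested beyond the omissions named. Single-cell omissions in turn moved the list median to between 0.045 (without Metaphase I replicate 3) and 0.21 for preleptotene to zygotene genes, 0.10 (without Metaphase I replicate 20) and 0.30 (without Pachytene replicate 12) for metaphase entry genes, 0.092 (without Pachytene replicate 7) and 0.25 (without Metaphase I replicate 19) for centromere and kinetochore genes, 0.14 (without Metaphase I replicate 19) and 1.84 for immediate early genes, -1.97 (without Metaphase I replicate 3) and -0.15 (without Pachytene replicate 7) for acrosome and flagellum genes, -2.49 and -0.68 (without the same cells) for elongating spermatid markers, 0.00 (without Metaphase I replicate 19) and 4.25 (without Pachytene replicate 7) for Sertoli markers, and 0.89 and 2.10 (without the same cells) for the Leydig marker Star. Without the 8 libraries the medians were 0.034 for preleptotene to zygotene genes, 0.057 for cohesin, condensin and shugoshin genes, -0.17 for acrosome and flagellum genes, -0.60 for elongating spermatid markers, 0.28 for Sertoli markers and 1.12 for Star. With medians over cells, they were 0.00 for preleptotene to zygotene, immediate early, stress response, p53, Sertoli and mRNA decay genes (0.0027 for the last), -0.051 for synaptonemal complex genes, 0.29 for metaphase entry genes, -0.027 for acrosome and flagellum genes, -0.020 for piRNA genes, -0.33 for elongating spermatid markers and 0.41 for Star. Equal weight per cell gave 0.27 for metaphase entry genes, thinning gave 0.051 for preleptotene to zygotene genes, and no count minimum gave 0.20 for Leydig markers. Detection at 2 counts gave a median of 9418.5 genes per Metaphase I cell.

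Signs turned for single genes with ratios over 2-fold. Without replicate 19 the log2 ratio was -0.62 for Eif4ebp1 (3.04 at the other end of the omissions), -0.15 for Smc1a (2.83), -0.28 for Klf6 (4.85), -0.25 for Gapdh (1.90) and -0.23 for mt-Nd5 (1.28). Without the 8 libraries it was -0.034 for Ctsl, -0.20 for Smc1a, -0.36 for Klf6, -0.33 for Gapdh and -0.31 for mt-Nd5. With medians over cells it was -0.13 for Tex101, 0.31 for Odf1, -0.68 for Gapdh and -0.70 for mt-Nd5. For Ube2a it was 0.17 without the deepest cell of each group, and between -2.79 and 0.018 over single omissions. Depth limits genes of few counts, such as Ccna2 with 3 counts in Metaphase I, and the spread between animals was not measured.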

Other observations

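The tests below on Sertoli markers, immediate early genes and acrosome and flagellum genes were chosen after the results were seen. The carry-over test was fixed before its 37 genes were examined, but its split of replicates came from traces of Clu, Vim, Cst9 and Hspb1 already seen.

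Cells of both groups were also spread along PC2 (11.1% of variance). Its low end held the mitotic kinase genes Plk1 and Aurkb, and its high end held Dazl, a germ cell translation regulator, and Casp8ap2. Metaphase I replicates 13, 14 and 15 had scores of 112, 93.7 and 87.5, with Ccnb1 at 4.01, 3.92 and 7.96 CPM and summed recombination genes at 2667, 1921 and 2217 CPM. Metaphase I replicate 18 had a score of 81.0, with 68.4 CPM of Ccnb1 and 1639 CPM of recombination genes. Pachytene replicates 14 and 16 had scores of 84.8 and 78.1, with Ccnb1 at 36.4 and 12.7 CPM and recombination genes at 2148 and 2047 CPM. These were the 6 highest scores. The 3 lowest were those of Metaphase I replicates 6 and 9 and Pachytene replicate 11, at -68.6, -63.8 and -63.2, with Ccnb1 at 505, 450 and 344 CPM and recombination genes at 1276, 1270 and 1169 CPM. These genes were chosen after their values were seen, and no explanation was tested.

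Sertoli markers and immediate early genes were higher in the Metaphase I sum. A response to okadaic acid shared by the spermatocytes of many libraries is argued against only as the source of most differences over 2-fold. Leaving out replicate 19 cannot tell which cell in that library made its counts. Without replicate 19 only 2 of the 23 measured immediate early genes, Egr4 and Ccn1, were over 2-fold higher (log2 ratios 1.68 and 1.39, Egr4 chosen after its values were seen). For the 14 over 2-fold higher in the sum, the median number of the other 19 Metaphase I libraries that reached 10% of the level in replicate 19 was 0. These 14 were picked by a sum that replicate 19 dominates, so that number only describes where their counts lay. A smaller response across the list, and a response of Egr4 and Ccn1, stay open, with a list median of 0.37 without the 8 libraries and 0.14 without replicate 19. Outside replicate 19, Ccn1 was highest in replicates 18 and 17, at 11.9 and 9.16 CPM, with 5.60 CPM in replicate 5. Replicates 17 and 18 are among the libraries with Sertoli traces described below, so carry-over also stays open for Ccn1. Egr4 had 1.42 CPM in replicate 19 and up to 68.4 CPM elsewhere. Sertoli cell RNA in 1 library may account for the markers, since replicate 19 held 96.3% of their summed Metaphase I counts. Clu, Cst9 and Vim were the most abundant. The 20 most abundant Pachytene genes stood in replicate 19 at a median of 45.9% of the level of the other Metaphase I cells. A germ cell and a Sertoli cell sharing the library could give this, and elutriation by size would not remove such a pair with certainty. The 45.9% cannot decide it, because replicate 18, with only 292 CPM of Sertoli markers, was also low in such genes. Ldhc was at 5453 CPM in replicate 18 and 8295 in replicate 19, Meig1 at 2389 and 2097, and Lyar at 2425 and 2448. A response of a Sertoli cell or of a germ cell in replicate 19 to the drug or to dissociation stays open, untested.

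Traces of Sertoli transcripts were seen in Metaphase I replicates 13 to 18 and 20. For 37 other genes at 200 CPM or more in replicate 19 and a mean of 1 CPM or less in Pachytene, 44.0% of gene and library pairs had a count in these 7 libraries and 4.95% in replicates 1 to 12, a ratio of 8.88. Together the genes lay at 0.387% of their level in replicate 19, highest in replicate 18 at 318 CPM. Depth differs, but the summed level was 30.4 CPM or more in each of the 7 and 22.9 or less in each of the 12. Carry-over of RNA or barcodes when amplified cDNA was pooled is a candidate explanation. Sertoli RNA in a shared cell suspension would give the same values and stays open. Pachytene replicate 7 also held Sertoli markers, at 205 CPM, against 292 CPM in Metaphase I replicate 18. Its source was not tested, and the 37 genes, picked for a low Pachytene mean, cannot show it.

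Acrosome and flagellum genes were lower in the Metaphase I sum. A lower level in Metaphase I cells at large stays open: the log2 ratio of medians over cells had a median of -0.027 over the list and -0.056 over the 11 genes over 2-fold lower in the sum, but for these 11 it ran from -2.53 to 0.31, with quartiles of -0.86 and -0.013. The elongating spermatid markers had -0.33 by medians over cells and -0.60 without the 8 libraries. Some cells outside the 8 still held these markers, at 1278 CPM in Pachytene replicate 5, 886 in Pachytene replicate 1 and 737 in Metaphase I replicate 16. The -0.60 can therefore still reflect a few cells. The number and depth of the libraries that hold spermatid transcripts could account for part of the acrosome and flagellum difference. The list median was -0.17 without the 8 libraries over 0.3% X-linked counts. The 11 genes, picked by the sum, were then all still below 0, with a median of -0.40. Of the 9 elongating spermatid markers over 2-fold lower in the sum, 7 were below 0 (median -0.73). Of the 8 libraries, Metaphase I replicate 19 had the lowest acrosome and flagellum level of all cells. In the others of the 8, recombination genes lay at 610 to 936 CPM, against group medians of 1381 and 1476 CPM. Their Y-linked shares were 0.0566% to 0.109%, against medians of 0.000960% and 0.000685%. Whether these others hold spermatids or spermatocytes with spermatid RNA was not tested, and elutriation by size does not exclude either.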
